A study of Arabidopsis thaliana with 30 samples.

How the data were processed

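RNA of whole seedlings was sequenced in 30 libraries, 3 for each of 5 lines under mock treatment and under 50 µM antimycin A for 5 h. Groups and replicate numbers were taken from the titles of the samples, and the columns of the tables were matched to them by name. The columns taken for snrk1a and SnRK1aOX carry the names kin10-2 and KIN10V17 instead. They were assigned to these lines because KIN10 is another name of SnRK1a and, for SnRK1aOX, because the name carries no mutant allele, which no label states. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a standard Illumina preparation, and nothing there records strand. Reads were aligned with Bowtie 0.12.2 to the build TAIR10, per the submitters' processing notes. The tools that counted, normalised and tested the genes are not given in the sources used here.

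There is 1 deposited table per line. Each holds, for every listed gene, a signal per library, which from the file headers and the values is a read count that the authors adjusted for library size within that table. The authors also deposited a log2 fold change of antimycin A over mock, and p-values and q-values of a test that is not named. Every listed gene has a q under 0.05 and an absolute log2 fold change over 1 in either direction, from the values. The ratios of q to p and rank imply that the authors had tested 23742 genes in WT, 23834 in snrk1a, 23758 in jmj15, 23783 in crf6 and 23728 in SnRK1aOX. Genes that did not pass were not analysed here, so no gene can be called unchanged, and a list member that is not listed was either below the thresholds or not measured.

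Depth per library is unknown, since the values are adjusted and cover selected genes. Sums over the listed genes move with the number of genes listed, so they are not given. In 6 of 30 libraries at least 97% of low values lay within 0.1 of whole multiples of 1 step, and in the others they did not, so that whole reads were not recovered. In those 6 libraries 81.2% of the low values that lay within 0.1 of a whole multiple were even multiples. The limit of 97% was chosen after the data had been seen.

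The design, the gene lists, the rule for named genes and the alternatives, except those said to be chosen later, were fixed before the data were examined. That design foresaw a test of raw counts, or limma for adjusted values, and the authors' calls as the main result where a table holds only selected genes. The last case applied, so counts of changed genes are those of the authors, and a refit with limma 3.58.1 (R 4.3.3) gives the changes of single genes with their standard errors. The refit used log2(value + 1), a linear model of treatment within each table and empirical Bayes moderation with trend as in limma, two-sided, and its Benjamini-Hochberg adjustment counted the implied number of tested genes. Since 1 was added to each value, changes of genes with low values are understated. The refit passed an adjusted p of 0.05 for 2653 of the listed genes in WT, 3392 in snrk1a, 2189 in jmj15, 2538 in crf6 and 1463 in SnRK1aOX.

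The tables were normalised separately, so tests were made within a table. A difference between a line and WT is the difference of their within-table changes, tested in limma over the genes listed in both tables, with a Benjamini-Hochberg adjustment over those genes. The comparison of mock lines with mock WT that had been designed was not tested, because it would set levels across tables. Such levels are described for the heat shock list, the mitochondrial dysfunction list and the larger responses of jmj15, without a test. Overlaps of calls were tested with Fisher's exact test, two-sided, with the 27444 nuclear protein-coding genes of the annotation as background, per direction. Each line has its own mock libraries, so these overlaps share no controls.

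The 20 gene lists cover mitochondrial dysfunction genes, alternative respiration, complex III, NAC regulators, starvation genes, glutathione transferases, heat shock, the unfolded protein response, immunity, jasmonate, ethylene, rapid stress, abscisic acid, cytokinin, auxin, cell wall expansion, photosynthesis, root cell types, iron and the study's module. Each was tested per line and direction with Fisher's exact test against the same background, 200 tests adjusted together, of which 66 passed. Differences of lists between lines were tested with Fisher's exact test on the genes called and with camera in limma. Product families of at least 15 genes in the annotation, 238 in all, were tested in the same way over 2380 tests, a step chosen after the data had been examined. Near-identical copies (LHCB1.2 to LHCB1.5, LHCB2.2, LHCB2.3, RBCS1B, RBCS2B, RBCS3B, SAUR20 to SAUR24, GSTU2, GSTU4, GSTU6, GSTU11, GSTU18, GSTU25, GSTF3 and GSTF7) were left out in 1 alternative, since reads could be split between them. Of these, LHCB2.2 and LHCB2.3 go beyond the families that had been named before.

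Genes were named by rule. In WT these are the 10 largest increases and 10 largest decreases among genes past the threshold with a level at or above the table's median and no overlap between treated and mock libraries. In each other line and each difference they are the 5 largest per direction by the same rule, and every listed member of the study's module and 2 to 4 members of each other list in WT were added. The authors' identifiers were matched to the annotation of TAIR10.1 for symbols, which gave 6229 of 6297 identifiers. No coordinates are given, because the authors' build was TAIR10.

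Both fitting steps were tested on simulated tables with 200 changed genes before use. At a change of log2 2 the refit recovered 92.4% in WT, 89.4% in snrk1a, 83.3% in jmj15, 92.4% in crf6 and 77.3% in SnRK1aOX. The test of differences recovered 92.4% of differences of log2 2 for jmj15 and 92.4% for SnRK1aOX, and at most 0.446% of unchanged genes were called in any step. Within a simulation every gene had the same dispersion, so these shares need not hold for the real genes, whose spread varies. With 200 changed genes the adjusted threshold is also easier to pass than where few genes differ. Alternatives were a pseudocount of 0.1, an adjusted p of 0.01, a replicate block, changes centred on the shared genes, no genes among the 0.1 with the lowest levels, another background, camera with an estimated correlation and the removal of each library in turn. Other splits of the libraries were drawn up to 100 per comparison, and for differences these reassigned residuals between the lines within treatment. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.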

Results

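RNA was sequenced from whole Arabidopsis thaliana seedlings, 10 days old, of 5 lines: wild type (WT), the mutants snrk1a, jmj15 and crf6 (alleles snrk1a-2, jmj15-2 and crf6-2 in the sample titles), and a line that overexpresses SnRK1a (SnRK1aOX). SnRK1 is a protein kinase of energy sensing, JMJ15 is a histone demethylase of the jumonji family and CRF6 is a transcription factor of the cytokinin response factor family. Seedlings of each line were moved to liquid medium and given 50 µM antimycin A, an inhibitor of complex III of the mitochondrial respiratory chain, for 5 h, or a mock treatment. Each of the 10 groups held 3 libraries, 30 in all. The comparisons ask how the transcripts of each line respond when respiration is blocked, and whether SnRK1, JMJ15 and CRF6 alter that response.

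Each line has 1 table of normalised read counts, and it lists only genes that the authors had called changed, at a q under 0.05 and an absolute log2 fold change over 1. Sequencing depth is unknown, because a sum over selected genes is not the depth of a library. KIN10 (AT3G01090) and KIN11 (AT3G29160), which encode the catalytic subunits of SnRK1, JMJ15 (AT2G34880) and CRF6 (AT3G61630) are not among the listed genes analysed here, so no targeted gene could check the line labels. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Counts of higher and lower genes and list members are those of the authors' deposited tables, and each list was tested with Fisher's exact test. That test takes the members of a list as independent, while they were measured in the same libraries and may vary together. Its p-values may therefore be too small. Changes given with ± are differences of log2(value + 1), antimycin A minus mock, with the standard error of a limma refit (n = 3 libraries per group). Levels are mean ± SD of the normalised count (n = 3). The largest increases and decreases named below are ranked by the authors' log2 fold change among genes at or above the table's median level. They also had no overlap between treated and mock libraries, so genes outside these limits may have changed more.

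In WT, transcripts of heat shock proteins, of detoxifying enzymes and of the mitochondrial stress response were higher with antimycin A, and transcripts of cell wall enzymes, of cytokinin signalling and of root cell types were lower. HSP21 (AT4G27670), a small heat shock protein of the chloroplast, rose from 18.1 ± 18.4 to 1026 ± 329. NRT2:1 (AT1G08090), a high-affinity nitrate transporter of the root, fell from 824 ± 451 to 22.1 ± 3.88, a log2 change of -5.04 ± 0.38. The authors' deposited table listed 3481 genes for WT, 1383 higher and 2098 lower. In 156 genes of this table every library of 1 group was listed at 0, against 0 such genes in each other table. The tables write their lowest values differently, so this does not show that genes lacked signal in WT alone. In jmj15 the treated libraries had 0 values at 0 and 148, 153 and 160 values just above it. Those of WT had 100, 100 and 175 values at 0 and 94, 96 and 0 just above it.

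**Figure D1:**
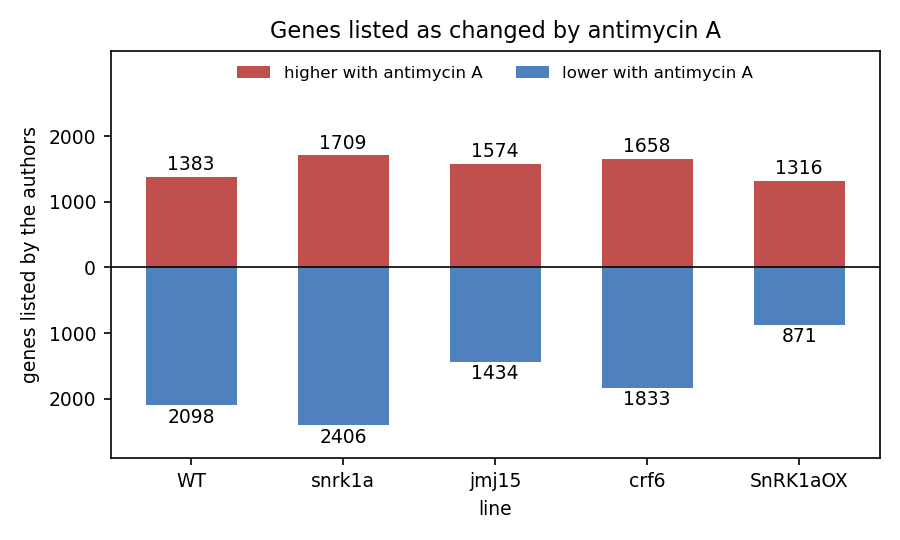
Number of genes (vertical axis) that the authors listed as higher (red bars, upward) or lower (blue bars, downward) with antimycin A in each line (horizontal axis). The downward bars run from 871 in SnRK1aOX to 2406 in snrk1a, and the upward bars from 1316 in SnRK1aOX to 1709 in snrk1a.

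Heat shock genes were prominent among the largest increases in WT. HSP22 (AT4G10250), a small heat shock protein of the endoplasmic reticulum, rose by 5.67 ± 0.48, HSP17.6II (AT5G12020) by 5.01 ± 0.50, HSP26.5 (AT1G52560) by 4.77 ± 0.46 and HSP17.6C (AT1G53540) by 4.40 ± 0.39. HSFA2 (AT2G26150), a heat shock transcription factor, rose by 4.28 ± 0.36. On the heat shock list 17 of 19 members were higher and 2 were not listed (adjusted p = 3.73e-19). AT1G07400, a chaperone of the HSP20 family that is not on the list, rose by 4.27 ± 0.31. The other large increases were those of GSTU3 (AT2G29470, 6.03 ± 0.79), a glutathione transferase, GRX480 (AT1G28480, 5.28 ± 0.56), a glutaredoxin, and AT4G37220 (4.31 ± 0.41).

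Genes of the mitochondrial stress response rose. On the list of mitochondrial dysfunction genes, which mark signalling from mitochondria to the nucleus, 15 of 22 members were higher and 7 were not listed (adjusted p = 3.77e-14). Among them were CYP81D11 (AT3G28740, 3.25 ± 0.17), ZAT12 (AT5G59820, 2.54 ± 0.23), UGT74E2 (AT1G05680, 1.95 ± 0.19) and SOT12 (AT2G03760, 1.95 ± 0.19). The alternative respiration list, which holds alternative oxidases and NAD(P)H dehydrogenases that bypass parts of the respiratory chain, had 5 of 12 members higher and 7 not listed (adjusted p = 0.000621). AOX1A (AT3G22370), an alternative oxidase, which takes electrons past complex III, rose from 25506 ± 6246 to 57930.4 ± 2922, a log2 change of 1.21 ± 0.21. AOX1D (AT1G32350) rose by 1.45 ± 0.28 and NDB2 (AT4G05020) by 1.41 ± 0.22, while AOX1B (AT3G22360) stood at 1.34 ± 0.43 with an adjusted p of 0.0965 in the limma refit. Of the 5 NAC regulators, transcription factors of this response, NAC053 (AT3G10500, 1.49 ± 0.16) and NAC013 (AT1G32870, 1.27 ± 0.16) were higher, and the list did not pass the test (adjusted p = 0.0641). Of 13 nuclear genes for complex III and cytochrome c, 1 was listed, QCR7-2 (AT5G25450) at 1.24 ± 0.40 with an adjusted p of 0.101 in the refit (list adjusted p = 0.835).

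Genes of the glutathione transferase and starvation lists were also higher. On the list of glutathione transferases, which attach glutathione to reactive compounds, 19 of 26 members were higher and 7 were not listed (adjusted p = 1.61e-18), with GSTU4 (AT2G29460, 2.23 ± 0.26) and GSTF8 (AT2G47730, 2.11 ± 0.16) among them. Of the starvation genes known to respond to SnRK1, 11 of 19 were higher and 8 were not listed (adjusted p = 1.83e-09). DIN2 (AT3G60140), a beta-glucosidase, rose by 3.31 ± 0.53, and BCAT2 (AT1G10070) (2.52 ± 0.27) and DIN4 (AT3G13450) (2.15 ± 0.21), both of branched-chain amino acid metabolism, and DIN1 (AT4G35770) (2.14 ± 0.24) rose as well.

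Several lists of defence and hormone genes had more members higher in WT than chance gives. On the immunity list 8 of 22 members were higher and 14 not listed (adjusted p = 2.92e-05). FRK1 (AT2G19190, 2.07 ± 0.25), WRKY46 (AT2G46400, 2.18 ± 0.36) and WRKY70 (AT3G56400, 1.66 ± 0.21) were higher, and PBS3 (AT5G13320) stood at 2.27 ± 0.76 with an adjusted p of 0.118 in the refit. The jasmonate list had 9 of 22 members higher (adjusted p = 2.49e-06) and 1 lower (adjusted p = 1.00). JAZ9 (AT1G70700), a repressor of the pathway, rose by 3.01 ± 0.20 and AOC2 (AT3G25770), an enzyme of jasmonate synthesis, by 2.34 ± 0.22, while VSP1 (AT5G24780) changed by -2.12 ± 0.50. The rapid stress list had 8 of 14 higher (adjusted p = 4.90e-07), with ERF109 (AT4G34410, 5.63 ± 0.86), CML39 (AT1G76640, 4.69 ± 0.59) and CML37 (AT5G42380, 3.10 ± 0.51). On the abscisic acid list 5 of 14 were higher (adjusted p = 0.00139), including HAI1 (AT5G59220, 2.04 ± 0.36), RAB18 (AT5G66400, 1.75 ± 0.34) and NCED3 (AT3G14440), an enzyme of abscisic acid synthesis (1.27 ± 0.18). RD29B (AT5G52300) stood at 1.57 ± 0.51 with a refit adjusted p of 0.102. The ethylene list had 3 of 14 members higher, ERF6 (AT4G17490, 2.53 ± 0.18), ERF2 (AT5G47220, 1.18 ± 0.15) and ERF1 (AT3G23240, 1.03 ± 0.27), and did not pass the test (adjusted p = 0.0817). The unfolded protein response list did not pass in either direction. ERDJ3A (AT3G08970, 1.48 ± 0.25) and BZIP60 (AT1G42990, 1.04 ± 0.18) were higher and CRT1A (AT1G56340, -1.37 ± 0.13) and CNX1 (AT5G61790, -1.16 ± 0.15) lower, with 8 of 12 members not listed (adjusted p = 0.280 for higher and 0.505 for lower).

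Growth-related transcripts fell in WT. Of the genes for cell wall expansion, 8 of 17 were lower and 9 were not listed (adjusted p = 7.09e-05). They included the expansins EXPA11 (AT1G20190, -3.19 ± 0.18), EXPA15 (AT2G03090, -2.97 ± 0.30) and EXPA5 (AT3G29030, -2.42 ± 0.26) and the xyloglucan enzyme XTH17 (AT1G65310, -2.32 ± 0.18). On the cytokinin list 5 of 14 were lower and 9 not listed (adjusted p = 0.00963). Among them were the response regulators ARR6 (AT5G62920, -2.57 ± 0.26), ARR5 (AT3G48100, -1.54 ± 0.19) and ARR4 (AT1G10470, -1.10 ± 0.17) and the receptor AHK4 (AT2G01830, -1.64 ± 0.15). CYP735A2 (AT1G67110), an enzyme of trans-zeatin synthesis, fell from 1098 ± 484 to 63.3 ± 25.9. The auxin list had 5 of 17 members lower (adjusted p = 0.0227) and 2 higher (adjusted p = 0.454). IAA6 (AT1G52830, -2.18 ± 0.41), SAUR20 (AT5G18020, -2.11 ± 0.38) and SAUR19 (AT5G18010, -1.66 ± 0.26) were lower, and GH3.3 (AT2G23170), which conjugates auxin to amino acids, rose by 1.87 ± 0.17. SAUR20 to SAUR24 are near-identical to SAUR19, so that their reads may be split between copies, and without them the list no longer passed the test (adjusted p = 0.149).

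Root transcripts fell in the same comparison. Of the markers of root hairs and endodermis, 9 of 9 were lower (adjusted p = 8.32e-10), with CASP4 (AT5G06200, -3.80 ± 0.40), PER64 (AT5G42180, -2.90 ± 0.27) and COBL9 (AT5G49270, -2.62 ± 0.55). This fall was measured in the same whole seedlings as those of the cell wall and cytokinin genes. On the iron list 3 of 12 members were lower (adjusted p = 0.147) and 1 was higher (adjusted p = 0.802). IRT1 (AT4G19690), the main iron transporter of the root epidermis, fell from 679.5 ± 609 to 16.2 ± 12.8, and FRO2 (AT1G01580), the root iron reductase, stood at -2.35 ± 0.69 with a refit adjusted p of 0.0674. BHLH100 (AT2G41240) was listed at 0 in the treated libraries and BTS (AT3G18290) rose by 1.07 ± 0.14. The other largest decreases were those of AT3G01260 (-5.25 ± 0.40), GSTF14 (AT1G49860, -4.44 ± 0.26), a glutathione transferase that is not on the list of them, AT1G34040 (-4.01 ± 0.36) and AT3G19430 (-3.99 ± 0.42). The cell wall genes XTH31 (AT3G44990, -3.67 ± 0.23), XTH12 (AT5G57530, -3.61 ± 0.54) and EXT13 (AT5G35190, -3.44 ± 0.50) were also among them. Photosynthesis genes had 1 of 22 members higher and 0 lower (adjusted p = 1.00 and 0.749), the higher one being LHCB2.3 (AT3G27690, 1.21 ± 0.33), a near-identical copy of other light-harvesting genes.

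Some of these single-gene calls were lost when 1 library was left out, for most of them any of several, and such fits also have less power. Leaving out 1 library ended the refit call of IRT1 (without antimycin A replicate 1 or 2 or mock replicate 1 or 3), COBL9 (without antimycin A replicate 1 or 2 or mock replicate 1) and VSP1 (without antimycin A replicate 1 or 2 or mock replicate 1 or 2). It also ended that of AOX1D (without antimycin A replicate 1 or 2), RAB18 (without antimycin A replicate 2), ERF1 (without antimycin A replicate 1, 2 or 3 or mock replicate 2 or 3) and LHCB2.3 (without antimycin A replicate 1 or 2 or mock replicate 1, 2 or 3). The direction was kept in each case. In those fits the IRT1 change in WT had adjusted p values from 0.0685 to 0.120, and the RAB18 change in WT one of 0.0529 (limma). Over all fits that left out 1 library the log2 change ranged for COBL9 from -3.20 to -2.06, for VSP1 from -2.55 to -1.89, for AOX1D from 1.11 to 1.75, for ERF1 from 0.79 to 1.19 and for LHCB2.3 from 0.89 to 1.53. Of the genes that missed the threshold, without mock replicate 1 AOX1B passed it at 1.71 with 0.0419 as adjusted p, QCR7-2 at 1.74 with 0.00358, RD29B at 2.07 with 0.0284 and PBS3 at 3.03 with 0.0349. Without mock replicate 2 FRO2 passed it at -3.26 with 0.00373, and PBS3 stood at 1.32.

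**Figure D2:**
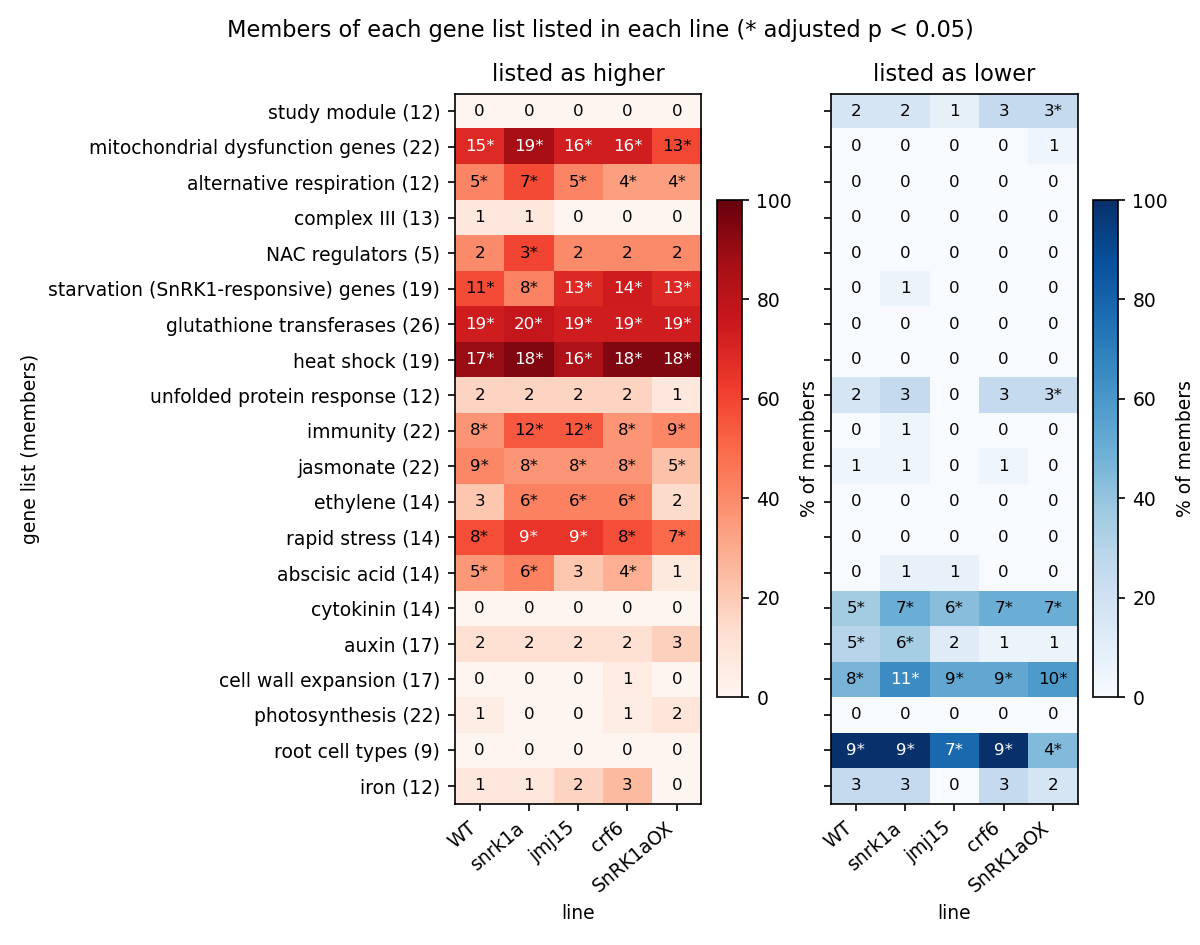
Number of members of each of the 20 gene lists (vertical axis, members in brackets) listed as higher (left) or lower (right) with antimycin A in each line (horizontal axis), with colour giving the percent of members and a star an adjusted p under 0.05. Heat shock genes run from 16 to 18 of 19 higher, and root markers from 4 to 9 of 9 lower.

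Of the study's module and its relatives, the genes listed in any line were cytokinin response factors, and all were lower. CRF1 (AT4G11140) was listed as lower in all 5 of the authors' deposited tables. In the refit it changed by -1.21 ± 0.27 in WT, -1.16 ± 0.26 in snrk1a and -1.43 ± 0.30 in crf6, and stood at -1.27 ± 0.42 in jmj15 (adjusted p = 0.149, and -0.79 without antimycin A replicate 1) and -1.28 ± 0.31 in SnRK1aOX (adjusted p = 0.0610). CRF3 (AT5G53290) was lower in WT (-1.02 ± 0.20), crf6 (-1.42 ± 0.23) and SnRK1aOX (-1.53 ± 0.25), and CRF2 (AT4G23750) in snrk1a (-1.20 ± 0.19), crf6 (-1.19 ± 0.16) and SnRK1aOX (-1.41 ± 0.22). The CRF1 call ended in WT without antimycin A replicate 1 or mock replicate 1 or 2, in snrk1a without mock replicate 1 or 2 and in crf6 without antimycin A replicate 3 or mock replicate 1 or 3. The CRF3 call ended in SnRK1aOX without antimycin A replicate 2 or mock replicate 3. In those fits the adjusted p reached 0.0746 for the CRF1 change in WT, 0.0700 for the CRF1 change in snrk1a, 0.0796 for the CRF1 change in crf6 and 0.0789 for the CRF3 change in SnRK1aOX (limma). Lower members of this list numbered 2 of 12 in WT (adjusted p = 0.505), 2 in snrk1a (0.568), 1 in jmj15 (0.833), 3 in crf6 (0.109) and 3 in SnRK1aOX (0.0177), a difference between lines that was not tested.

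Much of the response was shared between lines. Of 6297 genes listed in any line, 1125 were listed in all 5, 660 of them higher in every line and 465 lower in every line. Another 2297 genes were listed in 1 line, which does not show that the lines differ there, since a gene that misses the authors' thresholds in a line has no values to test. The tables were normalised separately, so differences between lines were tested with limma as differences of the within-table changes over the genes listed in both tables. All of these differences use the same WT libraries. Overlaps of higher or lower genes are counted over the nuclear protein-coding genes of the annotation, so their totals lie below those of the full tables.

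In snrk1a, genes of the heat shock, glutathione transferase and mitochondrial dysfunction lists rose, and cell wall and root genes fell. The authors' deposited table listed 4115 genes for snrk1a, 1709 higher and 2406 lower. The largest increases were those of GSTU3 (6.01 ± 0.57), HSP17.6A (AT5G12030, 5.18 ± 0.71), HSP22 (5.14 ± 0.43), ACA2 (AT2G28210, 4.93 ± 0.63), a carbonic anhydrase, and HSP26.5 (4.73 ± 0.42). The largest decreases were those of CYP702A5 (AT4G15393, -5.13 ± 0.45), AT3G01260 (-4.82 ± 0.30), the glutathione transferase GSTF14 (-4.13 ± 0.36), XTH31 (-4.07 ± 0.38) and AT1G52060 (-3.92 ± 0.33). Higher members numbered 18 of 19 on the heat shock list (adjusted p = 1.43e-19), 19 of 22 on the mitochondrial dysfunction list (3.73e-19) and 20 of 26 on the glutathione transferase list (1.76e-18). They numbered 8 of 19 on the starvation list (adjusted p = 3.81e-05) and 12 of 22 on the immunity list (7.24e-09). Lower members numbered 11 of 17 for cell wall expansion (adjusted p = 1.24e-07), 7 of 14 for cytokinin (0.000318) and 9 of 9 root markers (2.62e-09), all measured in the same samples. On each of the starvation, immunity, jasmonate and abscisic acid lists 1 member was lower. In the limma refit DIN2 rose by 3.22 ± 0.60 (adjusted p = 0.00436), while DIN4 stood at 1.08 ± 0.38 (adjusted p = 0.114), BCAT2 at 1.33 ± 0.67 (adjusted p = 0.435) and DIN1 at 1.18 ± 0.55 (adjusted p = 0.343). These 3 values rested on single libraries of snrk1a. Without antimycin A replicate 3 they were 0.60, 0.53 and 0.53, and without mock replicate 1 BCAT2 stood at 0.82 and DIN1 at 0.74. DIN4 passed the test without antimycin A replicate 2 (1.49, adjusted p = 0.0142). The other higher counts were 7 of 12 for alternative respiration (adjusted p = 9.70e-06), 3 of 5 for NAC regulators (0.00707) and 8 of 22 for jasmonate (0.000119). In snrk1a there were also 6 of 14 for ethylene (adjusted p = 0.000380), 9 of 14 for rapid stress (1.24e-07) and 6 of 14 for abscisic acid (0.000380). On the auxin list 6 of 17 were lower (adjusted p = 0.00810, and 0.201 without the near-identical SAUR copies).

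Between snrk1a and WT the tables shared, among nuclear protein-coding genes, 945 higher genes (70.2% of 1347 in WT, 56.6% of 1670 in snrk1a), where 82.0 were expected by chance (odds ratio 82.3). They also shared 1472 lower genes (70.2% of 2097 in WT, 61.2% of 2406 in snrk1a), where 184 were expected by chance (odds ratio 61.6). Fisher's exact p of this and each further overlap with WT lay below the smallest number the software holds, against a background of 27444 nuclear protein-coding genes. By limma 0 of the 2440 genes listed in both tables differed between snrk1a and WT (smallest adjusted p = 0.153), and 184 had an unadjusted p under 0.05 (7.54%). Chance gives 5% of unselected genes, while these had to pass the thresholds in both tables, so the 2 shares are not directly comparable. On simulated tables of this size the test recovered 92.4% of differences of log2 2 and 40.3% of differences of log2 1. The count was 1 without mock replicate 2 of WT, antimycin A replicate 3 of snrk1a or mock replicate 1 of snrk1a, and 0 without each of the other libraries.

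In jmj15, genes of the mitochondrial dysfunction and glutathione transferase lists rose, several of them more than in WT, and heat shock genes rose, several of them less than in WT. The authors' deposited table listed 3008 genes for jmj15, 1574 higher and 1434 lower. The largest increases were those of GSTU3 (7.45 ± 0.66), AT1G71520 (5.70 ± 0.35), MAPKKK19 (AT5G67080, 5.12 ± 0.37), ABCG40 (AT1G15520, 5.00 ± 0.29), a transporter, and ASPGB1 (AT3G16150, 4.91 ± 0.30). The largest decreases were those of AT5G45950 (-3.94 ± 0.25), EXPA5 (-3.75 ± 0.25), CYP702A5 (-3.68 ± 0.46), GH9C2 (AT1G64390, -3.52 ± 0.12) and EXPA11 (-3.48 ± 0.13). Higher members numbered 16 of 19 on the heat shock list (adjusted p = 1.54e-16), 16 of 22 on the mitochondrial dysfunction list (9.23e-15) and 19 of 26 on the glutathione transferase list (1.80e-17). They numbered 13 of 19 on the starvation list (adjusted p = 1.35e-11) and 12 of 22 on the immunity list (3.28e-09). Lower members numbered 9 of 17 for cell wall expansion (adjusted p = 3.13e-07), 6 of 14 for cytokinin (0.000179) and 7 of 9 root markers (2.37e-07), all measured in the same samples. The other higher counts were 5 of 12 for alternative respiration (adjusted p = 0.00119), 2 of 5 for NAC regulators (0.0817) and 8 of 22 for jasmonate (7.51e-05). In jmj15 there were also 6 of 14 for ethylene (adjusted p = 0.000274), 9 of 14 for rapid stress (6.91e-08) and 3 of 14 for abscisic acid (0.109), where 1 member was lower. With WT, jmj15 shared among nuclear protein-coding genes 957 higher genes (71.0% of 1347 in WT, 61.6% of 1553 in jmj15), where 76.2 were expected by chance (odds ratio 105). It also shared 1080 lower genes (51.5% of 2097 in WT, 75.3% of 1434 in jmj15), where 109.6 were expected by chance (odds ratio 75.0).

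Among the 2057 genes listed in both tables, 46 responded differently in jmj15 and WT (limma, adjusted p under 0.05), 34 with a more positive and 12 with a more negative change in jmj15. Of the 34, 33 rose more in jmj15 and NRT2:1 fell less. Of the 12, 9 rose less, 2 fell more, 4CL3 (AT1G65060) and EXPA8 (AT2G40610), and AT3G52350 rose in WT and fell in jmj15. NRT2:1, 4CL3, EXPA8 and AT3G52350 were chosen here after their values were seen. HSP22 changed by 5.67 in WT and by 1.26 in jmj15, where its refit adjusted p was 0.116 (0.00474, at 1.75, without mock replicate 2 of jmj15), a difference of -4.41 ± 0.67 (SE, adjusted p = 0.00876). HSP17.6II differed by -3.13 ± 0.71, HSP17.6C by -2.99 ± 0.57, AT1G59860, a chaperone of the HSP20 family, by -2.36 ± 0.45 and HSFA2 by -2.26 ± 0.46. AT1G07400, of the HSP20 family too and chosen here after its difference was seen, differed by -2.21 ± 0.48, a call kept in 4 of 12 fits that left out 1 library. In the other direction AT1G71520 differed by 3.23 ± 0.59, AT3G46080 by 2.52 ± 0.53, AGC2-1 (AT3G25250), a protein kinase, by 2.43 ± 0.32 (adjusted p = 0.00876), ABCB11 (AT1G02520), a transporter, by 2.18 ± 0.40 and AT4G37030 by 2.13 ± 0.38.

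With each table's changes centred on the median of the shared genes, which lay 0.14 higher in jmj15, 28 genes differed, 14 in each direction. NRT2:1 was no longer called (2.67 ± 0.62 from 2.81 ± 0.62, adjusted p = 0.0560), and the calls of the other genes named so far were kept. At an adjusted p under 0.01 without centring 5 genes differed. The count of 46 moved when 1 library was left out, in fits that also have less power. It was 5, 7 and 13 without antimycin A replicate 1, 2 or 3 of WT, and 30, 11 and 118 without mock replicate 1, 2 or 3 of WT. It was 6 and 6 without antimycin A replicate 1 or 2 of jmj15 and 14 without mock replicate 1 of jmj15. The differences of HSP22 and AGC2-1 stayed past the threshold in all 12 fits that left out 1 library, and those of the other genes named by rule in 3 (HSP17.6II and AT3G46080) to 7 (ABCB11) of them. The call of EXPA8 was kept in 8 of these fits, that of AT3G52350 in 3, that of NRT2:1 in 2 and that of 4CL3 in 1.

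Of the 16 heat shock genes listed in both tables, 6 rose less in jmj15 over all genes tested and 13 adjusted over the list alone (Fisher's exact test of the list, adjusted p = 5.80e-09), and centring kept all 6. Camera, which compares a list with the other genes, called this list with a preset correlation of 0.01 between genes (adjusted p = 1.01e-20) but not otherwise (adjusted p = 0.331 with an estimated correlation). The change was smaller in jmj15 for 15 of them, with a median difference of -1.74. Against the same WT libraries it was also smaller for 14 of 17 in snrk1a (median difference -0.40, adjusted p = 0.705 with an estimated correlation), 17 of 17 in crf6 (median difference -0.98, adjusted p = 0.342 with an estimated correlation) and 17 of 17 in SnRK1aOX (median difference -1.06, adjusted p = 0.342 with an estimated correlation). In these lines 0 heat shock genes differed over all genes tested, and 0, 0 and 7 adjusted over the list alone. Whether jmj15 differed from them was not tested. With levels set across the separately normalised tables, relative to the median of the shared genes, these genes lay 2.83 above WT in the mock libraries of jmj15 and 1.18 above it in the treated ones.

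Of 15 mitochondrial dysfunction genes, 6 rose more in jmj15 and 7 adjusted over the list alone, with a median difference of 0.86 (Fisher's exact test, adjusted p = 2.43e-06, and adjusted p = 0.477 with an estimated correlation in camera). The change was larger for 15 of them, and also for 14 of 15 in snrk1a (median difference 0.60, adjusted p = 0.523 with an estimated correlation), 15 of 15 in crf6 (median difference 0.22, adjusted p = 0.705 with an estimated correlation) and 9 of 13 in SnRK1aOX (median difference 0.15, adjusted p = 0.896 with an estimated correlation), where 0 differed over all genes tested or over the list alone. With levels set across the separately normalised tables, relative to the median of the shared genes, this list's median lay -0.89 from WT in mock jmj15. In treated jmj15 it lay -0.23 from WT, so the larger rise came with lower mock levels and not with higher treated ones. In jmj15 UGT74E2 differed by 1.97 ± 0.29, ZAT12 by 1.47 ± 0.35, SOT12 by 1.12 ± 0.25 and CYP81D8 (AT4G37370), chosen after its values were seen, by 1.97 ± 0.38. Without 1 library these calls were kept in 12, 3, 3 and 5 of 12 fits. Centring, which takes 0.14 off each difference, kept 3 of the 6 calls, those of UGT74E2, CYP81D8 and GSTU25 (AT1G17180), and ended 3, with ZAT12 at 1.33 ± 0.35 (adjusted p = 0.0847), SOT12 at 0.98 ± 0.25 (adjusted p = 0.0765) and GSTU24 at 0.84 ± 0.23 (adjusted p = 0.0896). Before it GSTU24 (AT1G17170) differed by 0.98 ± 0.23. Of 19 glutathione transferases, 5 rose more and 5 adjusted over the list alone, with a median difference of 0.49 (Fisher's exact test, adjusted p = 0.000251, and adjusted p = 0.705 with an estimated correlation in camera). GSTU4 differed by 1.88 ± 0.32, a call kept in 9 of 12 fits, and 2 of these 5, GSTU24 and GSTU25, also stand on the mitochondrial dysfunction list. Centring kept 3 of the 5 and ended those of GSTU24 and GSTU22 (AT1G78340), which stood at 1.35 ± 0.32 from 1.48 ± 0.32 (adjusted p = 0.0574). GSTU22, GSTU24 and GSTU25 are named here after their values were seen. Fisher's exact test still called both lists (adjusted p = 0.00458 and 0.00639 after centring). With a preset correlation camera called both lists. With an estimated one it called no list in any line.

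**Figure D3:**
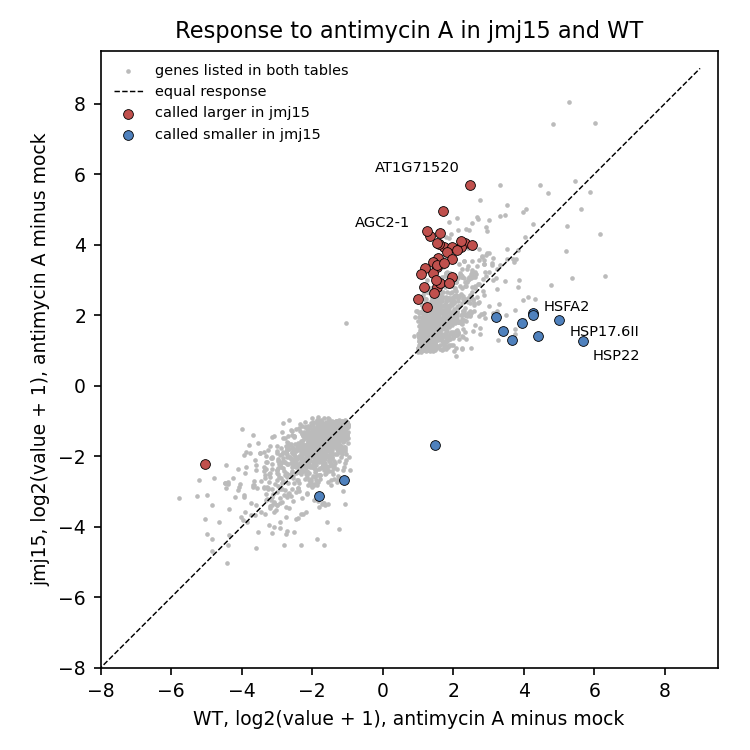
Change with antimycin A of each of the 2057 genes listed in both tables, as the difference of mean log2(value + 1), in WT (horizontal axis) and jmj15 (vertical axis), with the 46 genes that differed in colour and a dashed line of equal response. HSP22 lies at 5.67 in WT and 1.26 in jmj15, below the line, and AT1G71520 at 2.47 and 5.70, above it.

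In crf6, genes of the heat shock, glutathione transferase and mitochondrial dysfunction lists rose and the cell wall, cytokinin and root genes fell. The authors' deposited table listed 3491 genes for crf6, 1658 higher and 1833 lower. The largest increases were those of HSP21 (4.89 ± 0.44), GRX480 (4.63 ± 0.59), HSP22 (4.53 ± 0.51), GSTU3 (4.22 ± 0.41) and AT4G37220 (4.07 ± 0.53). The largest decreases were those of CYP702A5 (-4.15 ± 0.48), XTH31 (-3.88 ± 0.23), the glutathione transferase GSTF14 (-3.70 ± 0.58), NRT2:1 (-3.68 ± 0.43) and AT1G77520 (-3.58 ± 0.71). The AT1G77520 call ended without mock replicate 1 or 3 (-4.52 to -3.04 over the fits). Higher members numbered 18 of 19 on the heat shock list (adjusted p = 1.29e-19), 16 of 22 on the mitochondrial dysfunction list (1.71e-14) and 19 of 26 on the glutathione transferase list (3.70e-17). They numbered 14 of 19 on the starvation list (adjusted p = 7.10e-13) and 8 of 22 on the immunity list (9.89e-05). Lower members numbered 9 of 17 for cell wall expansion (adjusted p = 2.19e-06), 7 of 14 for cytokinin (6.44e-05) and 9 of 9 root markers (2.58e-10), all measured in the same samples. The other higher counts were 4 of 12 for alternative respiration (adjusted p = 0.0133), 2 of 5 for NAC regulators (0.0861) and 8 of 22 for jasmonate (9.89e-05). In crf6 there were also 6 of 14 for ethylene (adjusted p = 0.000337), 8 of 14 for rapid stress (1.88e-06) and 4 of 14 for abscisic acid (0.0229). On the jasmonate list 1 member was lower, and on that of cell wall expansion 1 was higher.

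With WT, crf6 shared among nuclear protein-coding genes 1045 higher genes (77.6% of 1347 in WT, 64.4% of 1623 in crf6), where 79.7 were expected by chance (odds ratio 153). In addition, both listed 1370 lower genes (65.3% of 2097 in WT, 74.8% of 1832 in crf6), where 140.0 were expected by chance (odds ratio 102). By limma 0 of the 2440 genes listed in both tables differed between crf6 and WT (smallest adjusted p = 0.996), and 110 had an unadjusted p under 0.05 (4.51%). This share too is of genes selected in both tables, so it does not show that crf6 responds as WT does. On simulated tables of this size the test recovered 89.4% of differences of log2 2 and 49.3% of differences of log2 1. These shares too may overstate the power, since the simulated genes shared the same dispersion (median SE of a real difference 0.435). The count was 3 without mock replicate 3 of WT and 0 without each of the other libraries. As lists, heat shock genes rose less and mitochondrial dysfunction genes more than in WT by camera with a preset correlation (adjusted p = 3.05e-14 and 0.0372). Neither was called otherwise (adjusted p = 0.342 and 0.705 with an estimated correlation).

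In SnRK1aOX, genes of the heat shock, glutathione transferase, starvation and mitochondrial dysfunction lists rose and cell wall and cytokinin genes fell, and fewer genes were listed as lower than in any other line. The authors' deposited table listed 2187 genes for SnRK1aOX, 1316 higher and 871 lower. The largest increases included GSTU3 (5.57 ± 0.84), AT3G25190 (4.74 ± 0.88), BGLU28 (AT2G44460, 4.53 ± 0.25) and CYP94B3 (AT3G48520, 4.40 ± 0.51), an enzyme of jasmonate breakdown, and AT1G18020 stood at 4.67 ± 1.27 with a refit adjusted p of 0.0930 (0.0169, at 6.26, without antimycin A replicate 1). The largest decreases were those of GH9C2 (-3.02 ± 0.14), XTH31 (-2.92 ± 0.22), AT5G45950 (-2.91 ± 0.17), EXPB3 (AT4G28250, -2.73 ± 0.36) and AT3G55230 (-2.46 ± 0.37). The call ended without antimycin A replicate 2 for GSTU3 (4.48 to 6.31 over the fits) and AT3G55230 (-2.88 to -2.24), and without antimycin A replicate 1 or 2 or mock replicate 3 for AT3G25190 (3.86 to 5.60). Higher members numbered 18 of 19 on the heat shock list (adjusted p = 4.30e-21), 13 of 22 on the mitochondrial dysfunction list (1.99e-11) and 19 of 26 on the glutathione transferase list (8.81e-19). They numbered 13 of 19 on the starvation list (adjusted p = 1.40e-12) and 9 of 22 on the immunity list (1.88e-06). Lower members numbered 10 of 17 for cell wall expansion (adjusted p = 1.65e-10), 7 of 14 for cytokinin (5.59e-07) and 4 of 9 root markers (0.000422), all measured in the same samples. On the mitochondrial dysfunction list 1 member was lower. The other higher counts were 4 of 12 for alternative respiration (adjusted p = 0.00630), 2 of 5 for NAC regulators (0.0603) and 5 of 22 for jasmonate (0.0102). In SnRK1aOX there were also 2 of 14 for ethylene (adjusted p = 0.335), 7 of 14 for rapid stress (7.06e-06) and 1 of 14 for abscisic acid (0.847). The unfolded protein response list had 3 of 12 members lower (adjusted p = 0.0177).

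With WT, SnRK1aOX shared among nuclear protein-coding genes 854 higher genes (63.4% of 1347 in WT, 66.0% of 1294 in SnRK1aOX), where 63.5 were expected by chance (odds ratio 101). Both lines also listed 653 lower genes (31.1% of 2097 in WT, 75.0% of 871 in SnRK1aOX), where 66.6 were expected by chance (odds ratio 52.1). Of the 1530 genes listed in both tables, 2 differed by limma, and both were chosen after their values were seen. APX2 (AT3G09640), an ascorbate peroxidase, rose less in SnRK1aOX (difference -3.66 ± 0.56 SE, adjusted p = 0.0372), and AT4G03470 rose in SnRK1aOX and fell in WT (difference 5.93 ± 0.98 SE, adjusted p = 0.0401). An unadjusted p under 0.05 was found for 148 genes (9.67%). The count was 1 without antimycin A replicate 1 or 2 of WT, 3 without mock replicate 2 of WT and 0 without each of the other libraries. It was 4 with 0.1 added in place of 1 and 0 without the 0.1 of genes with the lowest levels, to which both belong (mean levels 27.9 and 6.71). Each of the calls ended in 10 of the 12 fits that left out 1 library.

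For the remaining lists the mutants and SnRK1aOX gave small counts. Complex III genes were listed as higher in snrk1a (1 of 13) and in no other of these lines. On the unfolded protein response list, lower members numbered 3 of 12 in snrk1a (adjusted p = 0.201), 0 in jmj15 and 3 in crf6 (0.109), and higher members 2, 2, 2 and 1 in snrk1a, jmj15, crf6 and SnRK1aOX. Auxin genes were higher in snrk1a (2 of 17), jmj15 (2 of 17), crf6 (2 of 17) and SnRK1aOX (3 of 17). They were lower in jmj15 (2 of 17), crf6 (1 of 17) and SnRK1aOX (1 of 17) without passing the test (adjusted p = 0.493, 1.00 and 0.761). Iron genes were lower in snrk1a (3 of 12), crf6 (3 of 12) and SnRK1aOX (2 of 12) and higher in snrk1a (1 of 12), jmj15 (2 of 12) and crf6 (3 of 12), again without passing it (smallest adjusted p = 0.0856). Photosynthesis genes were listed as higher in crf6 (1 of 22) and SnRK1aOX (2 of 22, adjusted p = 0.562), and in no line as lower.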

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

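The tests of scaling and the test of the WT mock libraries on the heat shock list were chosen after the result was seen. Each result in this part was singled out because the response to antimycin A differed between a line and WT in a test of that difference.

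In jmj15, 46 genes responded differently from WT, and the median difference was -1.74 for the heat shock list, 0.86 for mitochondrial dysfunction genes and 0.49 for glutathione transferases. Of 100 splits of the libraries between the lines 1, the real one, gave as many genes (highest other 33). The share is under 0.05, which makes chance unlikely for the count but does not exclude it, since only 100 splits were drawn. List medians as large in size, not adjusted for the number of lists, came from 1 (highest other 1.62) for heat shock, 2 (highest other 0.87) for mitochondrial dysfunction genes and 9 (highest other 0.71) for glutathione transferases, where chance cannot be excluded. Without any 1 library the heat shock median lay between -2.07 and -1.31, which argues against 1 library. Centring takes the same 0.14, the median over genes listed in both tables, off each difference, so it is no separate test of scaling. Scaling of that size accounts neither for the heat shock median (-1.88 after it, median SE of single genes 0.51) nor for the size of the larger responses. Their median was 1.73 from 1.86 (SD between genes 0.62). Yet centring ended 20 of 34 such calls (adjusted p up to 0.0896) and left 14. The shift was measured on genes selected in both tables, so a larger one is not excluded. With levels set across separately normalised tables, the mock levels of the genes with larger responses lay -1.90 from WT in jmj15 against -0.54 in snrk1a, -0.45 in crf6 and -0.32 in SnRK1aOX, under 0.5 of the jmj15 shift in all 3 but on its side for 31 of 33, 27 of 34 and 27 of 33 genes (median differences 0.66, 0.51 and 0.52), and the genes were chosen by their difference in jmj15, which enlarges its shift, so this bound excludes nothing. For the heat shock list they lay 2.83 above WT in jmj15 and 0.68, 1.57 and 1.42 in snrk1a, crf6 and SnRK1aOX, under 0.5 of that in 1 line, while in treated libraries jmj15 lay 1.18 above WT (SD between genes 0.45) and -0.0564 from it for the larger responses, so the differences lie mainly in the mock libraries, and WT mock libraries that stand apart and an effect of the mutation cannot be told apart for either set.

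Single genes that differed in jmj15 were HSP22 by -4.41 ± 0.67 (SE), HSP17.6II by -3.13 ± 0.71, HSP17.6C by -2.99 ± 0.57, AT1G59860 by -2.36 ± 0.45 and HSFA2 by -2.26 ± 0.46. Those that differed in the other direction were AT1G71520 by 3.23 ± 0.59, AT3G46080 by 2.52 ± 0.53, AGC2-1 by 2.43 ± 0.32, ABCB11 by 2.18 ± 0.40 and AT4G37030 by 2.13 ± 0.38. In SnRK1aOX 2 genes differed from WT, APX2 by -3.66 ± 0.56 and AT4G03470 by 5.93 ± 0.98, and 2 of 100 splits gave as many genes (highest other 2). The share is under 0.05, but another split gave the same count and 3 unchanged genes were called in simulated tables of this size, so chance is not taken as excluded. Each call ended in 10 of 12 fits that left out 1 library.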

How the results depend on the processing

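The pseudocount and level filter for differences, centring for lists, the limma refit of the listed genes and camera with an estimated correlation were chosen after the data had been seen. No value reversed under any alternative run. With 1 library left out, 1891 of 2058 values of named genes kept their side of the threshold, 150 fell below it and 17 passed it, and of 144 values of named differences 76 fell below it. The genes that differed from WT ranged over those fits from 0 to 1 in snrk1a, 5 to 118 in jmj15, 0 to 3 in crf6 and 0 to 3 in SnRK1aOX. The listed genes also past a limma refit in SnRK1aOX numbered 1463 with all libraries and ranged from 578 to 1197. There were 578 without antimycin A replicate 2 and 920.0 without mock replicate 3, and 743 at an adjusted p under 0.01. Fewer libraries also give these fits less power, and the cause was not tested further. In jmj15 28 genes differed after centring, which takes 0.14 from each difference, and 5 at an adjusted p under 0.01. In SnRK1aOX 4 differed with a pseudocount of 0.1, 0 at an adjusted p under 0.01 and 0 without the 0.1 of genes with the lowest levels, which leaves out both genes. The cause of the others was not tested. Without near-identical copies the auxin list kept 3 lower members in WT and 3 in snrk1a and no longer passed, as fewer members were tested. Camera with a preset correlation also called lists that Fisher's exact test of differences did not, and the cause was not tested. For snrk1a, mitochondrial dysfunction genes (adjusted p = 9.44e-06), alternative respiration (0.00519) and glutathione transferases (0.0119) had a more positive change than in WT. Starvation genes (0.0386), heat shock (0.0305) and root cell types (0.0130) had a more negative one. The change was more negative in snrk1a for 8 of 8 starvation genes listed in both tables (median difference -0.43), and 0 were called. With an estimated correlation the adjusted p of this list was 0.705, and 47 of 100 splits gave a median as large in size. In the same camera test alternative respiration was more positive (adjusted p = 0.0156) and cell wall expansion more negative (0.0141) for jmj15. For crf6 mitochondrial dysfunction genes were more positive (0.0372), and heat shock (3.05e-14) and jasmonate (0.00219) more negative. For SnRK1aOX heat shock (3.05e-14), jasmonate (5.76e-05) and rapid stress (0.0242) were more negative. With an estimated correlation camera called no list, and the 3 of jmj15 had adjusted p = 0.477 for mitochondrial dysfunction genes, 0.705 for glutathione transferases and 0.331 for heat shock. Correlations of same-numbered libraries lay between -0.315 and 0.0969, so the numbers do not pair the samples. With a replicate block 0 genes differed in SnRK1aOX and 44 in jmj15, and 12 of 343 values of named genes fell below the threshold. Tools for raw counts, other size factors, a filter on low counts, a fit of all 30 libraries and tests of mock lines against mock WT were not run, because the values are adjusted per table, and an absolute log2 fold change of at least 1 is the authors' own selection. Changes below log2 1 lie outside the tables.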

Other observations

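The tests of product families, of the spread between replicates over all genes, of fold sizes by direction, of scaling in SnRK1aOX, of organelle carry-over and of the chromosome 2 insertion were chosen after the result was seen. Among product families of the annotation, lower genes in WT included 61 of 141 C1 domain proteins (Fisher's exact test, adjusted p = 9.38e-28), 45 of 125 leucine-rich repeat kinases (1.41e-16), 30 of 62 peroxidases (4.90e-15) and 30 of 78 SAUR-like proteins (6.20e-12). Secreted and cell wall enzymes were lower too, with 24 of 77 GDSL lipases (1.61e-07), 14 of 28 expansins (2.92e-07) and 12 of 28 xyloglucan endotransglucosylases (1.90e-05). Higher families in WT were tau glutathione transferases with 8 of 16 members (1.69e-05, with 2 lower at 0.860), WRKY factors with 11 of 56 (0.00143), MATE transporters with 11 of 55 (0.00124) and multidrug resistance-associated transporters with 6 of 15 (0.000993). Pentatricopeptide repeat proteins, which act on RNA of mitochondria and plastids, were listed less often than chance gives, with 1 of 200 higher (0.0110) and 2 of 200 lower (0.000875), which says only that few passed the thresholds.

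Transcripts with identifiers of the mitochondrial genome were listed as higher in every line, 36 of 37 listed in WT, 30 in snrk1a, 21 in jmj15, 35 in crf6 and 22 in SnRK1aOX, with 7 of 58 listed in all lines. A greater share of organelle RNA in treated libraries would raise plastid transcripts too, and these were listed as higher in 1 line, snrk1a (9). In crf6 1 was listed, as lower (log2 -3.60 in the authors' deposited table), which goes against carry-over, and in the other lines 0, too few to tell, so that carry-over and a rise of mitochondrial RNA cannot be told apart. Reads shared with the copy of mitochondrial DNA on chromosome 2 are needed if that copy is involved. In WT 28 loci whose identifiers start with AT2G07 were higher. These loci were taken for the copy by identifier alone, so some may lie outside it. A rise of mitochondrial RNA may also give the same values through shared reads. An effect of antimycin A on mitochondrial RNA stays open and was not tested.

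The table of SnRK1aOX lists the fewest genes, and of 907 genes listed as lower in all 3 mutants it lists 53.7%, against 93.7% in WT, while of 956 higher genes it lists 78.1% against 80.9% (exact McNemar p = 8.25e-87 and 0.0768, over genes, which are not independent replicates). Over genes listed in all lines absolute changes in SnRK1aOX minus WT had a median difference of -0.0775 (bootstrap SE 0.0145). It was -0.30 (SE 0.0301) for genes that fell and 0.0518 (SE 0.0200) for those that rose, so smaller falls may account for the low count, but these genes had to pass the thresholds in SnRK1aOX, which hides smaller changes, so the bound of -0.1 set beforehand excludes nothing. A shift of the whole table would list more rises, which were not listed more often, and would move both sizes alike, where their ratio was 0.174. But these are the same selected genes, and those that rose had greater spread, which may keep rises from being listed. The median difference over genes listed in both tables lay 0.10 above 0, so scaling is not excluded. For the genes that fell the SD within groups was 0.973 times that of WT (1.32 for those that rose) and over all these genes 1.18 times that of WT, yet snrk1a, with the most genes, had a higher SD (0.332 against 0.311), and the thresholds also hide greater spread, so spread and an effect of the line cannot be told apart.

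For the changed genes of each line, 10 splits of 6 libraries are too few for a share under 0.05. The real split, 1 of them, gave 2653 genes past the refit in WT, 3392 in snrk1a, 2189 in jmj15, 2538 in crf6 and 1463 in SnRK1aOX, and the highest other split gave 0 in each line. The authors had selected these genes on the real split, so this contrast was set in advance and says nothing about chance. For snrk1a against WT, 100 of 100 splits gave at least as many as the 0 genes that differed (highest other 2). For crf6 100 of 100 gave at least as many as its 0 (highest other 2). Every split reaches a count of 0, so this says nothing about chance. For the other lines' lists, of 100 splits, those with a heat shock median as large in size numbered 48 (highest other 1.17) for snrk1a, 7 (highest other 1.47) for crf6 and 3 (highest other 1.46) for SnRK1aOX. For mitochondrial dysfunction genes they were 4 (highest other 0.72), 37 (highest other 0.58) and 60 (highest other 0.68), not adjusted for the number of lists.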
